A study of Mus musculus with 14 samples.

How the data were processed

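RNA was measured in whole ileum of C57BL/6N mice, an inbred laboratory strain, in 14 libraries: 4 from untreated mice at postnatal day 14 (P14), 4 from untreated mice at day 24 (P24), 3 from mice injected with phosphate-buffered saline (PBS) and 3 from mice injected with recombinant mouse IL-22 (rmIl22). Per the labels' protocols, the injected mice received 0.1 µg of rmIl22 per g body weight in 100 µL, or saline alone, at days 14 and 15 and were killed at day 16. The labels call the replicates biological. The age field gives day 14 for the PBS mice and day 24 for the rmIl22 mice, which disagrees with the stated day 16, and groups were taken from the sample titles. Total RNA was depleted of ribosomal RNA and made into strand-specific libraries, per the labels' protocols.

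The authors' deposited expression table holds TPM (transcript abundance scaled for gene length and to the same total in every library) for every gene symbol and library. The submitters' processing notes name STAR 2.4.0f, HTSeq 0.6.1p1, FastQC 0.11.2 and the mm10 genome. The submitters' notes also name DESeq2 1.14, and the authors' 2 deposited tables of comparisons give a log2 fold change and an adjusted p-value per gene with no replicate values. Which step each tool served, the annotation release and the strand setting of the counting are not given in the sources used here, so overlapping antisense genes and near-identical gene copies are uncertain. The comparison tables write decimal commas, which were read as decimal points. The columns of the P14 and P24 libraries carry the numbers 1, 2, 4 and 5 and 1, 2, 6 and 8, which are not the replicate numbers of the labels, so each such column was assigned to its group only. Libraries are named here by these column numbers.

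Depth was worked out from the TPM. All nonzero values of a library are whole multiples of what 1 read is worth for a gene, and whole reads (within 0.01 of a whole number) were recovered for all 31216 genes with any value above 0. The smallest whole numbers in proportion to a gene's values were taken, so whole values alone do not show that the reads are right. Genes whose reads share a common factor, or with reads in 1 library only, can be undercounted. On simulated data, 99.79% of 3804 genes were recovered exactly. The simulated means were alike in all libraries, so this does not cover genes read in 1 group only. The recovered totals ranged from 35.7 to 46.5 M reads per library, with a median of 42.7 M, and they count reads assigned to genes. Where a gene had no reads in a library, the floor was set at 3 reads, which covers counting error only. Reads of a pair of libraries of the same group differed by far more than sampling noise, with a chi-square per degree of freedom from 30.89 to 254.6, so no library was counted as a copy of another. Of the table's 46882 entries, 27 whose symbols had been turned into date numbers were left out. They held at most 0.08% of the TPM of a library.

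The main test was limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step, on log2(TPM + 1), so the log2 fold changes understate the change of low genes. Each comparison was fitted on its own libraries. Genes were kept with a TPM of at least 1 in at least 4 libraries (P24 vs P14) or 3 (rmIl22 vs PBS), tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. In both comparisons, 35 gene lists (pathways, epithelial cell types and other cells that whole ileum can hold) were fixed before the data were examined. Lists with at least 3 tested genes went into limma's camera with its preset correlation of 0.01, adjusted over the lists of that comparison. Each list was run again with an estimated correlation and with limma's fry. The overlap of calls between the comparisons was tested with Fisher's exact test, two-sided, and the difference between both effects with a contrast in a fit of all 14 libraries. On simulated data built from these libraries, the test recovered 95.97% of genes changed 2-fold and 99.6% of those changed 4-fold in the age comparison (14671 to 14705 genes tested in 5 draws), and called 9 to 14 unchanged genes. In the rmIl22 comparison (14476 to 14551 genes) it recovered 88.51% and 99.2%, and called 18 to 34 unchanged genes. None of the 30 random lists of a draw was called in any of these draws. The simulated genes varied independently, with 1 dispersion for all genes of a comparison (0.011 for age, 0.0162 for rmIl22). Real list members vary together, with an estimated correlation of 0.63 for Paneth cell genes in the age comparison. The random lists therefore say nothing about false calls of real lists. The recovery rates leave out libraries that stand apart from their group and are a best case.

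The genes named in the text were chosen by a rule fixed before the data were examined. They are the 5 largest rises and 5 largest falls per comparison among called protein-coding genes with separate group values and a mean of at least 5 TPM in the higher group. Added to these were the 2 called members with the largest change of each list tied to the epithelium, IL-22, metabolism or lymphocytes and the largest called member of each other list (the largest in each direction where calls went both ways), and Muc3, Muc13, Muc1, Muc4, Muc2, Reg3b, Reg3g, Fut2, Il22 and Il22ra1 in any case. Not every gene picked by the rule is reported here. Other genes named were chosen after their values were seen, and this is said where they appear. Gene positions are from GENCODE M21 (the mm10 assembly), matched by symbol for 44027 of 46880 symbols (93.9%). Sex was read from Xist and the Y-linked Ddx3y.

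The alternatives tried were other pseudocounts and filters, median-scaled and quantile-normalised values, TPM without the mitochondrial and the 20 most abundant genes, other variance settings, sample weights, a fit of all libraries, the replicate number as a block (rmIl22 comparison), a stricter threshold of 1 on the log2 scale, and leaving out each library. Limma voom on the recovered reads and sex as a covariate were added after the data were seen. No count model was the main test because the deposited unit is TPM. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.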

Results

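Whole ileum, the last part of the small intestine, was profiled by RNA sequencing in 14 libraries. The series asks how the tissue differs before and after weaning and what interleukin-22 (IL-22) changes in it. IL-22 is a cytokine that acts on epithelial cells through the transcription factor STAT3. The title of the series ties it to the transmembrane mucin MUC17 on the surface of enterocytes. The deposited table has no Muc17 entry, and Muc3 was taken here as its mouse gene, an identity not given in the sources used here. There were 4 libraries from untreated mice at postnatal day 14 (P14), 4 at day 24 (P24), 3 from mice injected with saline (PBS) and 3 from mice injected with recombinant mouse IL-22 (rmIl22). Injections were given at days 14 and 15 and the tissue was taken at day 16. The deposited age field instead says day 24 for the rmIl22 mice and day 14 for the PBS mice. Depth was 35.7 to 46.5 M reads assigned to genes per library, as recovered from the deposited TPM. The p-values measure the spread between libraries of a group.

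The first comparison asked what differed between suckling (P14) and weaned (P24) mice. Muc3 (ENSMUSG00000037390.12, mm10 chromosome 5, 137134922 to 137149322, minus strand, protein coding) rose from 62.1 ± 7.76 TPM at P14 to 509 ± 458 TPM at P24 (mean ± SD, n = 4 each). Its log2 fold change was 2.67 (SE 0.40, adjusted p = 1.77e-04), and all P24 values lay above all P14 values. The spread at P24 came from library 2, with 1191 TPM against 233.1 to 358 TPM in the others. Muc13, the other abundant transmembrane mucin, rose from 1143 ± 236 to 1754 ± 461 TPM (log2 fold change 0.61, adjusted p = 0.0177). The Muc13 call was lost with no expression filter, with quantile normalisation and without P14 library 5, and its adjusted p ranged from 0.00143 to 0.101 over the alternatives. Of the 3 transmembrane mucins tested, 2 rose and 0 fell, also when adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.099). Muc3a, a separate gene of similar name chosen after its values were seen, stood at 5.38 ± 1.78 TPM at P24 and 7.29 ± 2.59 TPM at P14, and reads shared between both genes cannot be excluded. Muc1 (0.237 TPM at P14, 0.174 TPM at P24) and Muc4 (0.248 and 1.03 TPM) did not meet the expression filter and were not tested here. Muc4 had 45 to 100 reads in the P14 libraries and 227 to 298 reads in the P24 libraries, and the authors' deposited table gave it a log2 fold change of 2.34 (adjusted p = 4.37e-07). Muc2, the secreted mucin of goblet cells, did not pass the test (119 ± 101 against 125 ± 41.6 TPM, adjusted p = 0.556). Without P14 library 2 its adjusted p was 0.0241, within a range of 0.0241 to 0.907.

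Digestive and absorptive genes of the enterocyte changed in both directions. Sis, which encodes the adult disaccharidase sucrase-isomaltase (chromosome 3, 72888557 to 72967863), rose from 7.73 ± 0.87 to 1172 ± 425 TPM (log2 fold change 7.01, SE 0.21, adjusted p = 2.32e-10). Arg2, a mitochondrial arginase, rose from 0.14 ± 0.05 to 45.4 ± 8.2 TPM. Of 14 adult-type enterocyte genes, 11 rose, 0 fell and 3 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 4.74e-10, adjusted p = 0.34 with an estimated correlation). Of 17 suckling-type enterocyte genes, 16 fell, also when adjusted over the list alone (camera adjusted p = 3.26e-09, adjusted p = 0.25 with an estimated correlation). Lct, the milk sugar disaccharidase lactase, fell from 264 ± 204 to 2.43 ± 1.37 TPM, and Lgmn, a lysosomal protease, from 4390 ± 671 to 130 ± 21 TPM. The 5 largest falls were in Mamdc4, an apical endosomal protein of suckling enterocytes (1092 ± 167 to 2.71 ± 0.42 TPM, log2 fold change -8.20, adjusted p = 4.08e-12), the folate receptor Folr1 (1222 ± 163 to 4.93 ± 0.69 TPM, log2 fold change -7.69), Spp2 (log2 fold change -7.24), the lysosomal channel Mcoln3 (-7.15) and the sialic acid lyase Npl (-6.91). Among 19 brush border and microvillus genes, 8 rose and 1 fell (the same adjusted over the list alone), led by the actin nucleator Cobl (log2 fold change 2.35) and the microvillar myosin Myo1a (1.48), with camera adjusted p = 0.00325 and adjusted p = 0.56 with an estimated correlation. Cdhr5, a protocadherin that links microvilli, was the gene that fell (log2 fold change -0.45), and its call was lost on median-scaled TPM, where the counts were 10 and 0.

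Most genes of the IL-22 and STAT3 response list rose by P24. Reg3g, a secreted lectin that kills Gram-positive bacteria (chromosome 6, 78466269 to 78468872), rose from 72.2 ± 11.3 to 14280 ± 3614 TPM (log2 fold change 7.59, SE 0.18, adjusted p = 4.60e-11). Reg3b, a related lectin, rose from 752 ± 264 to 65870 ± 13230 TPM, with 54470 to 79180 TPM in the single P24 libraries. The acute-phase gene Saa1 (chromosome 7, 46740497 to 46742980) rose from 10.5 ± 2.7 to 1360 ± 517 TPM. How reads were divided between Saa1 and Saa2, and between the Reg3 genes, is uncertain. Of 23 IL-22 and STAT3 response genes, 16 rose and 1 fell (16 and 2 adjusted over the list alone), with camera adjusted p = 1.27e-12 and adjusted p = 0.25 with an estimated correlation. Il22 itself had 0 reads in all 4 P14 libraries and 7 to 63 reads in the P24 libraries (1.07 ± 1.11 TPM). Its P24 mean was at least 8.16-fold above 0.132 TPM, the highest value of 3 reads in a P14 library. Library 8 held 63 of the 103 reads, and without it the P24 mean was 0.537 TPM, at least 4.08-fold above that value. Libraries 1 and 8, with the most Il22 reads, also had the highest median of lymphocyte markers at P24. A two-sided exact permutation test on the 8 values gave p = 0.0286, the smallest that 70 regroupings allow. The near-copy Iltifb, chosen after its values were seen, had at most 2 reads in any library. The receptor chain genes Il10rb (64.1 to 28.4 TPM, log2 fold change -1.14) and Il22ra1 (85.3 to 61.0 TPM, -0.45, adjusted p = 0.0244) fell. The Il22ra1 call was lost on median-scaled TPM (adjusted p = 0.371, the upper end of its range, which began at 0.00128). Of 6 IL-22 source and receptor genes 0 rose and 4 fell, also adjusted over the list alone, and the list did not pass (adjusted p = 0.398).

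All 15 Paneth cell genes tested rose, also when adjusted over the list alone, including the antimicrobial gene Ang4 (log2 fold change 3.24, adjusted p = 2.32e-10). The camera adjusted p was 1.53e-17, with adjusted p = 0.25 with an estimated correlation, and near-identical members of the list share reads. Of 15 goblet cell genes, 10 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 5.74e-08, adjusted p = 0.29 with an estimated correlation). Zg16, a goblet cell lectin that binds bacteria, rose from 53.7 ± 57.0 to 4405 ± 373 TPM, and Retnlb, a bactericidal goblet cell protein, from 0.095 ± 0.15 to 51.6 ± 13.8 TPM. Of 27 mucin glycosyltransferase genes, 15 rose and 5 fell (the same adjusted over the list alone), with camera adjusted p = 1.57e-05 and adjusted p = 0.41 with an estimated correlation. Fut2, which adds the terminal fucose of mucins, rose from 3.08 ± 0.60 to 32.0 ± 9.0 TPM (log2 fold change 2.99), and B3galt5 rose by a log2 fold change of 3.37. The sialyltransferase gene St3gal1 fell from 170 ± 19.0 to 6.71 ± 1.37 TPM (log2 fold change -4.48, adjusted p = 2.23e-10).

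Lipid and bile acid genes moved in both directions. The ileal bile acid importer Slc10a2 rose from 9.87 ± 3.94 to 806 ± 82.7 TPM and the bile acid carrier Fabp6 from 632 ± 383 to 16890 ± 3201 TPM. Abcc2, another transporter gene of the list, fell (log2 fold change -3.62). Slc51b of the same list, chosen here after its values were seen, stood at 254 ± 97.1 TPM at P14 and 1583 ± 125 TPM at P24. Of 10 bile acid handling genes 5 rose and 3 fell (5 and 4 adjusted over the list alone), with camera adjusted p = 0.013 and adjusted p = 0.54 with an estimated correlation. The list's call was lost on median-scaled TPM (adjusted p = 0.14, range 0.00794 to 0.14) and with voom. Cholesterol synthesis genes rose in 16 of 22 cases and fell in 1 (17 and 1 adjusted over the list alone), with camera adjusted p = 2.73e-09 and adjusted p = 0.51 with an estimated correlation. Sqle (log2 fold change 2.55) and Hmgcs1 (1.84) rose most, and the Acat2 fall (-0.62) was lost on median-scaled TPM. Of 18 fatty acid oxidation and ketogenesis genes 13 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.00325, adjusted p = 0.54 with an estimated correlation). Acot1 fell by a log2 fold change of -3.59, while Angptl4 rose (1.42). Of 19 fat absorption genes 8 fell, among them the apolipoproteins Apoa4 (log2 fold change -5.69) and Apoc3 (-3.27), and 3 rose, including Fabp2 (3.15). These counts were the same adjusted over the list alone, and the list did not pass (adjusted p = 0.644). Of 18 xenobiotic genes 10 rose, led by the cytochrome Cyp2c65 (log2 fold change 3.22), and 2 fell, led by Ugt1a1 (-1.39). The counts were 10 and 4 adjusted over the list alone, with camera adjusted p = 1.08e-04 and adjusted p = 0.41 with an estimated correlation.

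Markers of other cells in the tissue differed as well. The plasma cell transcripts Igha (log2 fold change 3.46) and Igkc (3.11) and the cytotoxic granule gene Gzma (2.42) rose. The B and plasma cell list had 3 of 10 genes up, and the T, NK and innate lymphoid list 4 of 13 up and 1 down, both the same adjusted over the list alone. Their camera adjusted p was 0.00103 and 0.00639, adjusted p = 0.54 with an estimated correlation for both, and both calls were lost on median-scaled TPM. Lymphocyte markers also parted libraries within groups: relative to the PBS mean, the median B and plasma cell gene stood at 1.51 and 1.81 in P24 libraries 1 and 8 and at -1.26 and -1.27 in P24 libraries 2 and 6 (log2). At P14 it stood at -0.20 and -0.14 in libraries 1 and 5 and at -1.64 and -1.555 in libraries 2 and 4. P24 libraries 2 and 6 thus lay below P14 libraries 1 and 5. All 8 endothelial genes fell (Cdh5, -0.92), as did 9 of 11 neuron and glia genes (the receptor gene Ret, -2.68; 10 adjusted over the list alone) and 9 of 12 fibroblast and matrix genes (Col1a1, -1.13; 10 adjusted over the list alone). The camera adjusted p was 0.0326 for endothelium (lost without P14 library 5), 0.0326 for neurons and glia (lost without P14 library 1) and 0.0655 for fibroblasts. It was 0.56, 0.61 and 0.63 with an estimated correlation. The fibroblast list passed without P14 library 2 (0.0222) or 4 (0.0485) and on median-scaled TPM (0.0426), within a range of 0.0222 to 0.0985. Of 8 adipocyte genes 7 rose (Cfd, 4.09) and 1 fell (Cidec, -1.23), with camera adjusted p = 6.78e-04 (lost with voom, 0.0566) and adjusted p = 0.47 with an estimated correlation. Of 12 macrophage and dendritic cell genes 2 rose (Cd14, 2.18) and 4 fell (Csf1r, -1.92), and the list did not pass (adjusted p = 0.512). For adipocytes, macrophages and endothelium the counts were the same adjusted over the list alone.

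Proliferation genes rose in 11 of 20 cases (Birc5, 0.83) and fell in 3 (the replication helicase Mcm6, -0.70), immediate early genes rose in 7 of 11 (Fos, 3.08), tuft cell genes in 4 of 6 (Rgs13, 2.21) and red blood cell genes in 4 of 5 (Hba-a2, 1.13; 5 adjusted over the list alone). Their camera adjusted p was 2.70e-04, 1.21e-06, 0.00103 and 0.00694, and adjusted p = 0.54, 0.34, 0.40 and 0.54 with an estimated correlation. The red blood cell call was lost on median-scaled TPM. Smooth muscle genes (3 of 10 up, 1 adjusted over the list alone, Des at 0.94), mitochondrially encoded genes (1 of 8 up, mt-Cytb at 0.64) and MHC class II genes (0 of 10) had camera adjusted p from 0.0302 to 0.0467. These became adjusted p = 0.54 to 0.63 with an estimated correlation, and all 3 calls were lost on median-scaled TPM. The remaining lists did not pass. Of 11 stem cell genes 1 rose (Prom1, 1.37) and 4 fell (Tnfrsf19, -0.82), of 15 enteroendocrine genes 1 rose (Sct, 0.41, lost in the fit of all 14 libraries) and 6 fell (Chga, -0.79), and of 14 clock genes 2 rose (Arntl, 1.33) and 8 fell (Per2, -2.34). Of 19 interferon-stimulated genes 3 rose (Zbp1, 1.69) and 4 fell (Ifit1, -1.74; the list passed upwards without P14 library 5 or P24 library 6, adjusted p = 0.0412 and 0.02, range 0.02 to 0.604), of 6 granulocyte and mast cell genes 1 fell (Ccr3, -0.55, lost on median-scaled TPM), and of 2 pancreatic genes Clps rose (0.81) and Cela1 fell (-0.42, lost on median-scaled TPM). For the stem cell, enteroendocrine, macrophage and granulocyte lists the median member was lower while camera's direction was up, and for the interferon list the mean was negative and the median and camera's direction were positive.

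In all, 8546 of 14651 genes passed the threshold, 2146 higher (25.11%) and 6400 lower at P24, and 7679 of all genes tested had group values that did not overlap (chance gives 2.857% of genes). The median gene had a log2 fold change of -0.25 on the deposited scale. Relative to that median, with median-scaled TPM, 8468 genes passed, 4231 higher (49.96%) and 4237 lower, so the balance of directions depends on the scaling. Of 33 lists tested, 23 passed in camera, 0 with an estimated correlation and 19 in fry's directional test. Fry passed the IL-22 source and receptor (adjusted p = 2.63e-04), fat absorption (0.0187), fibroblast (0.0206) and clock (0.00241) lists, which camera did not. Brush border, proliferation, red blood cell and B and plasma cell lists passed camera but not fry (0.0644 to 0.0697). The same held for the T and NK cell, MHC class II, smooth muscle and mitochondrial lists (0.207 to 0.553 in fry). Of 69 named genes past the threshold, 54 kept the call in every alternative, and none reversed. A log2 fold change of at least 1 was reached by 715 higher and 1321 lower genes. In the authors' deposited table, 9474 of 23529 genes had an adjusted p under 0.05, 4748 higher and 4726 lower at P24. Of the 7845 of these tested here, 7465 had the same direction and 5904 passed, or 7695 with limma voom on recovered reads scaled to the median. The authors' deposited table gave Muc3 a log2 fold change of 3.35.

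**Figure D1:**
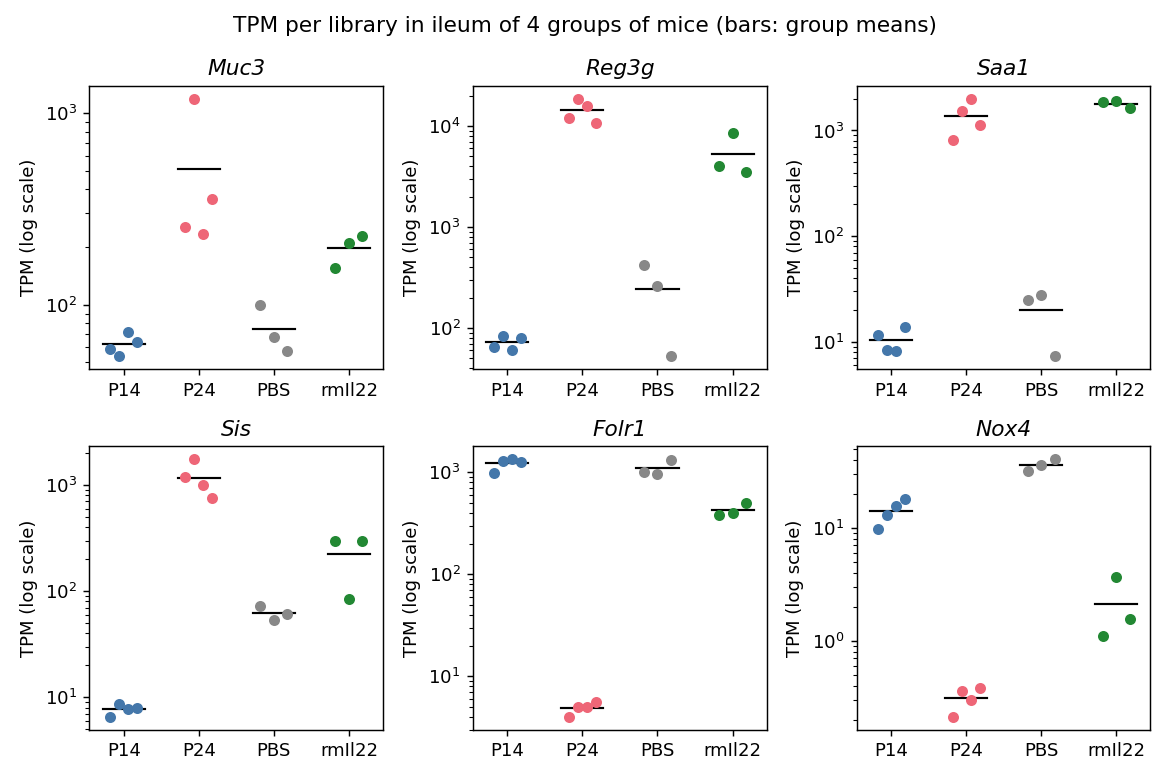
TPM per library on a log axis for 6 genes in the 4 groups of mice; each point is 1 library and each bar a group mean. Muc3 in P24 library 2 (1191 TPM) lies above the other P24 libraries (233.1 to 358 TPM), and Saa1 is near its P24 level in all rmIl22 libraries.

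The comparison of injected mice asked what IL-22 given before weaning changes in the ileum. Saa1 rose from 19.9 ± 11.1 TPM with PBS to 1795 ± 140 TPM with rmIl22 (mean ± SD, n = 3 each; log2 fold change 6.62, SE 0.44, adjusted p = 0.00432). Reg3g rose from 243 ± 183 to 5321 ± 2743 TPM (log2 fold change 4.77, SE 0.74, adjusted p = 0.0235), the amino acid transporter gene Slc6a14 by 4.17, the glutathione-degrading enzyme gene Ggt1 by 3.02 and Nos2, which makes nitric oxide, by 2.93. The glutathione transferase gene Gsta2 (chromosome 9, 78331018 to 78355788) fell from 73.1 ± 27.1 to 0.668 ± 0.294 TPM (log2 fold change -5.42, SE 0.27, adjusted p = 0.00193). Nox4, an NADPH oxidase gene (chromosome 7, 87246096 to 87398710), fell from 36.0 ± 4.3 to 2.12 ± 1.37 TPM (log2 fold change -3.65), and the amine oxidase gene Maob (-3.13), Akr1c19 (-3.02) and the glucose transporter gene Slc2a2 (-2.82) fell as well. Saa1 and Gsta2 were the 2 named genes of 23 past the threshold that kept the call in every alternative. The other 21 lost it in at least 1, most often when a PBS library was left out, and none changed direction.

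Muc3 rose from 75.0 ± 22.0 to 198 ± 37.6 TPM with rmIl22 (log2 fold change 1.41, SE 0.23, adjusted p = 0.0276), with all 3 rmIl22 libraries (155.3 to 227.4 TPM) above all 3 PBS libraries (57.5 to 99.6 TPM). The Muc3 call was lost in 11 of 20 alternatives, among them median-scaled TPM (adjusted p = 0.0569) and leaving out PBS library 1, 2 or 3 or rmIl22 library 3 (0.0651, 0.108, 0.157 and 0.095). Its log2 fold change stayed between 1.08 and 1.63 over them, and its adjusted p between 0.0119 and 0.168. Of 3 transmembrane mucins tested, 1 rose and 0 fell, also adjusted over the list alone, and the list did not pass (adjusted p = 0.0641). It passed without PBS library 1 (0.00676), rmIl22 library 1 (0.0402) or rmIl22 library 3 (0.0253), within a range of 0.00676 to 0.407. Muc13 (1362 ± 406 against 1295 ± 52.5 TPM, adjusted p = 0.976) and Muc2 (180 ± 34.3 against 200 ± 193 TPM, adjusted p = 0.903) did not pass. Muc1 (0.357 against 0.0864 TPM), Muc4 (1.17 against 0.375 TPM) and Il22 (0 to 2 reads with rmIl22, 0 to 3 reads with PBS) did not meet the expression filter and were not tested here. Muc4 had 103 to 541 reads with rmIl22 and 63 to 127 reads with PBS, and the authors' deposited table gave it a log2 fold change of 1.72 (adjusted p = 0.00858). Il22ra1 had 83.1 ± 18.0 against 99.4 ± 5.2 TPM (adjusted p = 0.501, and 0.046 without rmIl22 library 2, within a range of 0.046 to 0.849).

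The IL-22 and STAT3 response list had 4 of 24 genes up and 0 down (8 and 1 adjusted over the list alone), with camera adjusted p = 3.11e-06 and adjusted p = 0.64 with an estimated correlation. Its call was lost without rmIl22 library 2 (adjusted p = 0.118) and with sex as a covariate (0.0516). In library 2 the median gene of this list stood 1.96 above the PBS mean (log2), against 0.22 and 0.18 in libraries 1 and 3. Reg3b reached 27110 ± 20510 TPM with rmIl22, 16050, 50770 and 14490 TPM in libraries 1 to 3, against 2300 ± 1824 TPM with PBS, and did not pass (adjusted p = 0.107, range 0.0061 to 0.404), except in the fit of all 14 libraries (0.0061) and with the replicate number in the fit. Fut2 rose from 1.69 ± 0.28 to 11.2 ± 5.0 TPM (log2 fold change 2.09, adjusted p = 0.0234), and the sialyltransferase gene St3gal3 fell (-1.59). Of 25 mucin glycosyltransferases 2 rose and 2 fell (3 and 3 adjusted over the list alone), with camera adjusted p = 4.14e-04 upwards and adjusted p = 0.45 with an estimated correlation. Of 15 goblet cell genes 0 passed, also adjusted over the list alone, and the list as a whole was up (camera adjusted p = 3.48e-04, adjusted p = 0.64 with an estimated correlation). Its median stood 0.63 and 0.51 above the PBS mean in rmIl22 libraries 1 and 3 and 0.02 in library 2 (log2).

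Suckling-type enterocyte genes were lower with rmIl22. Of 17, 4 fell and 0 rose (13 and 0 adjusted over the list alone), with camera adjusted p = 2.72e-08 and adjusted p = 0.45 with an estimated correlation. Besides Nox4, the fetal serum protein gene Afp fell (log2 fold change -1.34). Of 14 adult-type enterocyte genes 1 fell, Slc2a2, and 0 rose (3 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.714). Sis, chosen here after its values were seen, stood at 297, 84.3 and 295 TPM in rmIl22 libraries 1 to 3, against 62.4 ± 9.6 TPM with PBS (adjusted p = 0.13). Cholesterol synthesis genes were higher as a list with 0 of 22 members past the threshold, also adjusted over the list alone. The camera adjusted p was 3.39e-08, and adjusted p = 0.64 with an estimated correlation. The groups overlapped, with the list's median at 0.28 in rmIl22 library 3 and 0.39 in PBS library 2, relative to the PBS mean (log2). Of 19 fat absorption genes 1 fell, the fatty acid transporter gene Slc27a4 (-0.70, adjusted p = 0.0493, lost in 15 of 20 alternatives, with a range of 0.012 to 0.201), and 5 adjusted over the list alone (camera adjusted p = 0.00131 downwards, adjusted p = 0.64 with an estimated correlation). The fat absorption median stood at -0.70, -0.09 and -0.53 in rmIl22 libraries 1 to 3 relative to PBS (log2). In the bile acid handling list the transporter gene Abcc2 fell (-1.40) and Slc51b rose (0.91), 1 of 11 genes in each direction. The counts were 2 and 2 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.873). Of 18 xenobiotic genes 3 fell, led by Cyp3a11 (-2.43), and 5 adjusted over the list alone, and the list did not pass (adjusted p = 0.288).

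Interferon-stimulated genes were lower with rmIl22 than with PBS. Of 17, 11 fell and 0 rose (13 and 0 adjusted over the list alone), with camera adjusted p = 1.02e-12 and adjusted p = 0.45 with an estimated correlation. On median-scaled TPM 5 of them fell. Ifit3 fell from 108 ± 29.6 to 16.7 ± 1.4 TPM (log2 fold change -2.59, SE 0.19, adjusted p = 0.00524). In the untreated mice Ifit3 stood at 35.3 ± 15.8 TPM at P14, below the PBS group. MHC class II genes and B and plasma cell genes were lower as lists, each with 0 of 10 past the threshold, also adjusted over the list alone. Their camera adjusted p was 0.00587 and 0.0126, and adjusted p = 0.73 and 0.84 with an estimated correlation. The groups overlapped: the median MHC class II gene stood at -0.243 in rmIl22 library 3 and -0.253 in PBS library 2, relative to the PBS mean (log2). The median B and plasma cell gene stood at -0.14 and -0.98 in the same libraries. The stem cell list (0 of 12, and 2 up adjusted over the list alone) was higher (camera adjusted p = 0.0164, adjusted p = 0.64 with an estimated correlation). Its median stood at 0.04 in rmIl22 library 2, below 0.20 in PBS library 3. The B and plasma cell and stem cell calls were lost without PBS library 1 (adjusted p = 0.112 and 0.074) and without rmIl22 library 2 (0.0771 and 0.0723). Cd14 rose (log2 fold change 1.60) and Csf1r, the growth factor receptor gene of macrophages, fell (-1.17), while Fos, an immediate early gene, fell (-1.48). Of 3 pancreatic genes tested Clps fell (-0.73, lost in 11 of 20 alternatives), and all 3 adjusted over the list alone (camera adjusted p = 0.0197, adjusted p = 0.45 with an estimated correlation). The pancreatic list's call was lost without PBS library 2 (0.05) and with sex as a covariate (0.0696), within a range of 0.00676 to 0.0696. The sex-linked list had 0 of 4 genes past the threshold (4 lower adjusted over the list alone), with camera adjusted p = 0.0197, and adjusted p = 0.70 with an estimated correlation. It was lost in 6 of 10 alternatives, with sex as a covariate (0.939) and without PBS library 1 (0.299), 2 (0.319) or 3 (0.16) or rmIl22 library 2 (0.0771) or 3 (0.0647). The other 23 lists had adjusted p from 0.0641 to 0.971. Besides the transmembrane mucin and Paneth cell lists, 9 of them passed in at least 1 alternative. These were neurons and glia (without PBS 3 or rmIl22 3, 0.0255 and 0.0383, and with sex as a covariate), fatty acid oxidation (without PBS 1 or 2, 0.0261 and 0.0262), granulocytes (without PBS 2 or rmIl22 1, 0.0346 and 0.00266), red blood cells (without PBS 2, 0.0162, and with sex as a covariate), proliferation (without PBS 1, 0.00676), fibroblasts (without rmIl22 2, 0.00275), xenobiotic genes (without rmIl22 1, 0.0107), T and NK cells (without rmIl22 3, 0.00414, and with sex as a covariate) and smooth muscle. The smooth muscle list passed in opposite directions with sex as a covariate and without rmIl22 library 1. Among the 23, the median was negative and camera's direction up for the adult-type, bile acid, tuft cell, fibroblast, smooth muscle and endothelium lists, with a negative mean for the last 2 as well. For immediate early genes the median was positive, and the mean and camera's direction were negative.

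In all, 389 of 14456 genes passed, 64 higher (16.45%) and 325 lower with rmIl22. Of all genes tested 3046 had group values that did not overlap (chance gives 10% of genes). With median-scaled TPM 296 passed, 71 higher (23.99%) and 225 lower. Of 35 lists tested, 12 passed in camera, 0 with an estimated correlation and 0 in fry's directional test, while fry's mixed test passed 14. Xist and Ddx3y marked 2 of the rmIl22 libraries (2 and 3) as female, 1 as male and all 3 PBS libraries as male, and with sex as a covariate, where the change rests on rmIl22 library 1 against PBS, 122 genes passed. The count was 14, 118 and 4 without PBS library 1, 2 or 3 and 129, 1324 and 121 without rmIl22 library 1, 2 or 3. The authors' deposited table for this comparison lists only genes with an adjusted p up to 0.00999, a stricter limit than the 0.05 used here. The authors' deposited table held 1102 genes at that limit, 371 higher and 731 lower, of which 1023 were tested here, all in the same direction, and 367 passed (312 on recovered reads). Muc3 was not listed in the authors' deposited table, which at that limit does not say whether it passed 0.05 there.

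**Figure D2:**
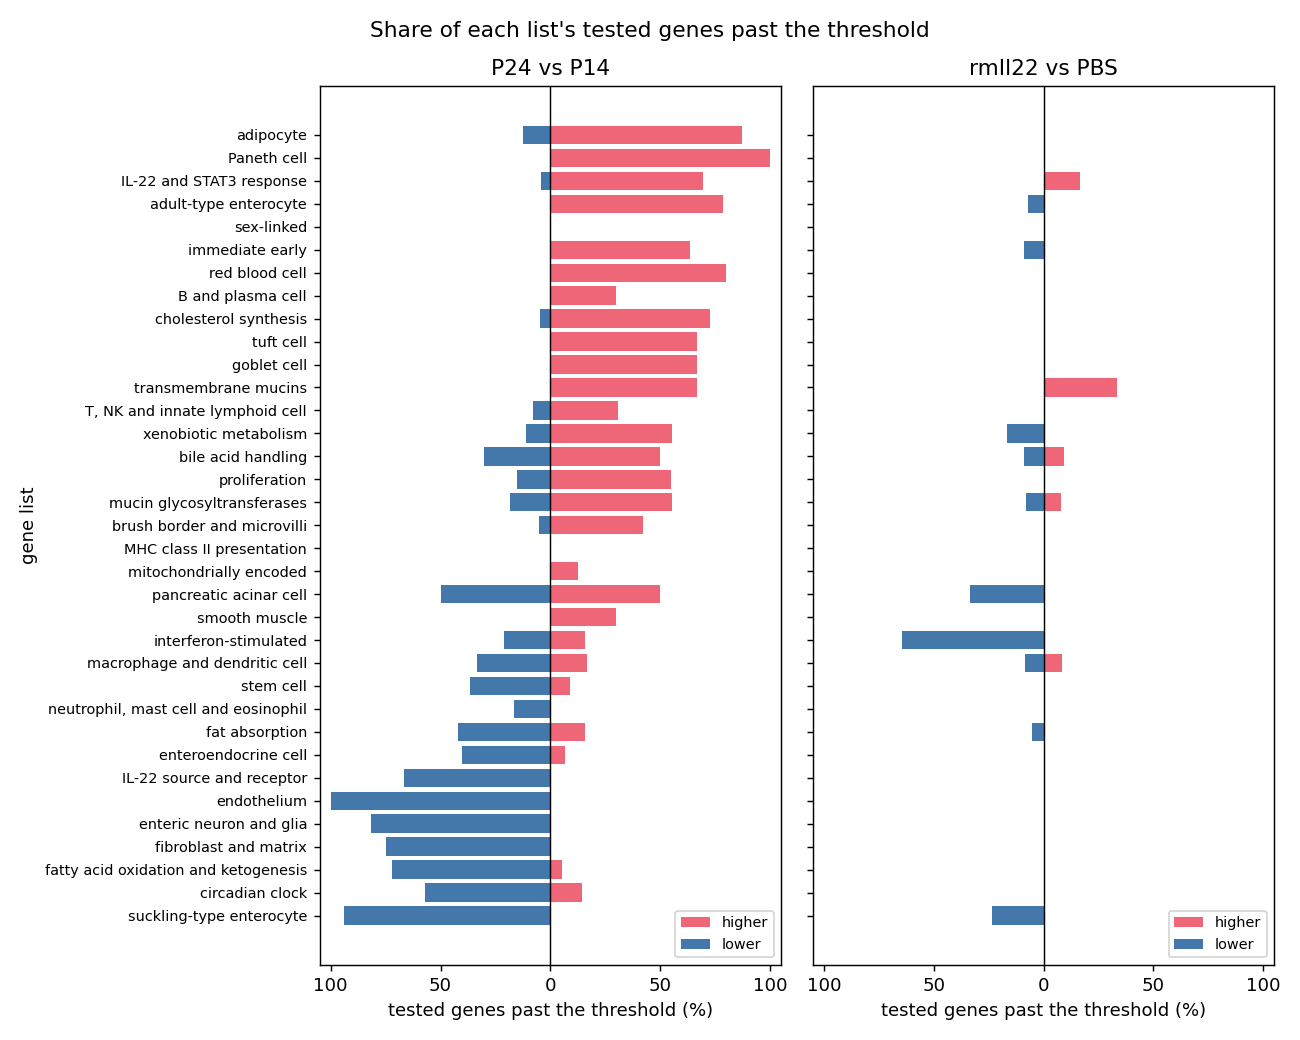
Share of each list's tested genes past the threshold, higher to the right and lower to the left (percent of the genes tested), for P24 vs P14 and rmIl22 vs PBS. All 15 Paneth cell genes were higher at P24 and 0 passed with rmIl22, while 11 of 17 interferon-stimulated genes were lower with rmIl22 (5 on median-scaled TPM).

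The last comparison asked how many genes that responded to rmIl22 also differed between the ages. The comparisons share no libraries, and 14161 genes were tested in both. Of the 64 genes higher with rmIl22, 55 (85.94%) were also higher at P24, against 9.093 expected from independent lists (odds ratio 37.9, Fisher's exact test, two-sided, p = 9.53e-38). Of the 315 lower with rmIl22 and tested in both, 279 (88.57%) were also lower at P24, against 140.2 expected (odds ratio 10.1, Fisher's exact test p = 1.27e-61). Genes are not independent replicates, so these p-values describe lists of genes. No gene was higher with rmIl22 and lower at P24, and 8 were lower with rmIl22 and higher at P24. As sets in the age comparison, the genes higher with rmIl22 had a median log2 fold change of 1.62 (camera p = 9.75e-39, p = 0.00304 with an estimated correlation) and those lower with it -1.75 (p = 3.68e-32, p = 0.0463 with an estimated correlation). Without PBS library 1 or 3 only 1 gene was called higher and the overlap of higher genes no longer passed (Fisher's exact test p = 0.143), and without PBS library 3 nor did that of lower genes (p = 0.0859).

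Effect sizes differed for many genes. Among the rmIl22 genes called in the same direction in both comparisons, the median ratio of the rmIl22 change to the age change was 0.542. The difference between both effects passed the threshold for 3734 of 15702 genes, and for 246 of 379 rmIl22 genes (64.91%). The change of Reg3g (adjusted p = 0.015 for the difference), Sis (1.06e-05) and Folr1 (6.02e-10) was smaller with rmIl22 than with age. Reg3g (243 TPM with PBS against 72.2 at P14) and Sis (62.4 against 7.73) already started higher with PBS. Their smaller change can come from that start. Folr1 did not start higher (1097 against 1222 TPM). The fall of Ifit3 (-2.59 against -0.65, adjusted p = 0.00409 for the difference), Cyp3a11 (-2.43 against -0.20, 0.0073) and Slc2a2 (-2.82 against -0.67, 0.00988) was larger with rmIl22. Fos (-1.48 against 3.08, 1.87e-04) and Clps (-0.73 against 0.81, 4.80e-04) changed in opposite directions. For Slc27a4 (-0.70 against 0.42) the difference passed (0.00699), while its age change did not (adjusted p = 0.0569). From Ifit3 to Slc27a4, the effects started from unlike levels, higher with PBS than at P14. Mean TPM was 108 against 35.3 (Ifit3), 6.51 against 1.84 (Cyp3a11) and 57.7 against 22.5 (Slc2a2). It was 67.2 against 10.6 (Fos), 86.25 against 46.1 (Clps) and 289 against 191 (Slc27a4). For Ifit3, Cyp3a11 and Slc2a2, the difference of effects can arise from such a start alone. It does not show an IL-22 effect beyond the age change in these genes. Fos, Clps and Slc27a4 stood below their P24 level with rmIl22 (23.3 against 89.3, 51.4 against 79.6 and 176 against 254 TPM). A higher start alone does not give a fall past the P24 level. For Muc3 (log2 fold change 1.41 with rmIl22 and 2.67 with age, difference -1.27, SE 0.59, adjusted p = 0.132), Fut2 (0.106), Saa1 (0.797), Gsta2 (0.237) and Nox4 (0.743) the difference did not pass, which does not show that the changes were equal. Paneth cell genes, all higher at P24, had 0 of 15 past the threshold with rmIl22, and their median was lower in all 3 rmIl22 libraries (-0.21, -0.41 and -0.35 relative to PBS, log2). The downward camera adjusted p was 0.0668. It passed on median-scaled TPM (0.0454), with voom (0.0314) and without PBS library 1 (0.00904) or 3 (0.0243), within a range of 0.00904 to 0.689.

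**Figure D3:**
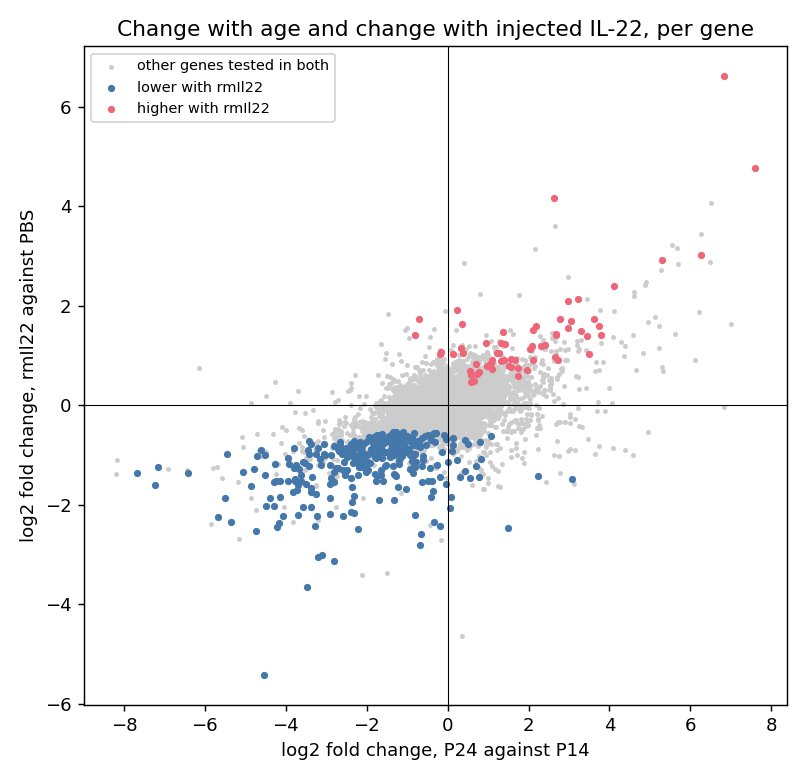
Log2 fold change with rmIl22 (vertical) against log2 fold change between P24 and P14 (horizontal) for the 14161 genes tested in both; each point is a gene, coloured where it passed in the rmIl22 comparison. Most coloured genes lie in the quadrants where both changes have the same direction, 55 higher and 279 lower past the threshold in both.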

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

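The test for a library far from the others of its group was chosen before the data were examined, and no test was added for this part. It compares the gap between the most extreme library and its nearest neighbour with the range of the group, and was applied to the named genes in the P14 and P24 groups. It was not applied to the PBS and rmIl22 groups of 3 libraries, so libraries that stand apart there were not marked. It marked 9 of 145 groups, where about 7.25 are expected by chance, so single values below carry little weight.

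P24 library 2 held 4 of the 9 values: Muc3 (1191 TPM, others 233.1 to 358), Hba-a2 (50.59 TPM, others 16.5 to 17.72), Lct (4.481 TPM, others 1.649 to 1.891) and Prom1 (40.61 TPM, others 32.84 to 33.82). Without this library the Muc3 log2 fold change was 2.15 (adjusted p = 6.91e-07, range over the alternatives 6.91e-07 to 0.005). The other P24 value was Ang4 in library 8 (733.2 TPM, others 660.6 to 663.8). At P14 they were Muc2 (270.2 TPM, others 58.03 to 81.95) and Arg2 (0.2192 TPM, others 0.1023 to 0.1185) in library 2, Igha in library 4 (2.536 TPM, others 1.073 to 1.316) and Zg16 in library 5 (138.3 TPM, others 18.5 to 37.03). No technical or biological explanation of these values was tested.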

How the results depend on the processing

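Voom on recovered reads, sex as a covariate, and median scaling and leaving out libraries for the tests that had not been planned with them were chosen after the data were seen. Age comparison: the count past the threshold was 2036 with a log2 fold change of at least 1 (715 higher, 1321 lower). Genes higher numbered 4231 (median-scaled), 4041 (quantile) and 4246 (voom), and lower 4237 (median-scaled) and 4264 (voom). Median scaling removes the shift of the median gene, and of the 6400 lower genes 4237 were shared with it. Without 1 library the counts were 7569 to 9086 (1940 to 2313 higher, 5532 to 7082 lower). Of 1531 values of named genes under alternatives, 1478 kept their side of the threshold, 52 lost the call, 1 gained it and 0 reversed.

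In the rmIl22 comparison, 98 genes passed with no filter (19 higher, 79 lower), 1058 in the fit of all 14 libraries (230, 828), 1381 with sample weights (397, 984), 122 with sex as a covariate (42, 80) and 212 with a log2 fold change of at least 1 (40, 172). Genes lower were 202 with quantile normalisation and 189 without the mitochondrial and most abundant genes. Without 1 library the counts were 4 (PBS 3) to 1324 (rmIl22 2), with 1 to 483 higher and 3 to 841 lower. Fewer libraries give less power, but the rise without rmIl22 library 2 does not follow from that. Without this library the median SE of the main calls fell, from 0.1672 to 0.1557 for higher genes and from 0.1567 to 0.1484 for lower genes. Why library 2 stood apart was not tested, nor was the cause of the other changes. Of 565 values of named genes, 454 kept their side, 108 lost the call, 3 gained it and 0 reversed. The shared percentage of rmIl22 calls was 67.75 to 100 for higher genes and 82 to 100 for lower genes without 1 library. The difference of effects had 2400 (without PBS 2) to 4997 (without rmIl22 2) genes. Lists past the threshold with an estimated correlation were 0 in both comparisons, and 0 with fry's directional test for rmIl22.

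No paired analysis was possible because the P14 and P24 column numbers are not replicate numbers. PBS and rmIl22 share the numbers 1 to 3. Residuals of same-numbered libraries correlated at -0.067, 0.333 and -0.049, and those of differently numbered libraries at -0.338 to 0.405. With 3 libraries per group these values cannot show whether the numbers pair the libraries, and the main fit assumed no pairing. With a replicate block 280 genes passed (59 higher, 221 lower; 42 and 188 shared), Reg3b gained the call, and Muc3, Slc51b, Slc27a4 and Clps lost it.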

Other observations

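The tests of the sex-linked genes, of the age in the deposited label, of rmIl22 libraries 1 and 3 alone and of a few abundant genes were chosen only after the results were seen. The comparisons below between PBS and P14 were not tested. PBS mice at day 16 differed from untreated P14 mice in several genes that also rose by P24. Zg16 stood at 1252 ± 292 TPM with PBS and 53.7 ± 57.0 TPM at P14, Sis at 62.4 against 7.73 TPM, Arg2 at 4.16 against 0.139 TPM and Fos at 67.2 against 10.6 TPM. Lct (697 against 264 TPM) and Akr1c19 (961 against 377 TPM) were higher with PBS as well, although both fall with age or rmIl22, while Afp was lower (6.63 against 68.3 TPM). The groups differ in age by 2 days and in injection, which cannot be told apart here. They also differ in sex, with 0 female and 3 male PBS libraries against 2 female and 2 male P14 libraries. Any other difference between the untreated and the injected sets of mice cannot be told apart from these either.

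rmIl22 library 2 differed from libraries 1 and 3 across many genes. The chi-square per degree of freedom of its reads was 254.6 against library 1 and 222.1 against library 3, and 49.72 between libraries 1 and 3. Examples were Lct with 523.3 TPM against 65.95 and 65.08, Apoa4 with 21530 against 3066 and 3473, and Slc10a2 with 35.7 against 366.2 and 236.8. Its medians relative to PBS (log2) for the xenobiotic and smooth muscle lists were -0.94 and -0.90, against 0.25 and 0.79 in library 1 and -0.08 and -0.17 in library 3. These genes were chosen after their values were seen.

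Across the 14161 genes tested in both comparisons, the rmIl22 change and the age change correlated at a Pearson r of 0.552 and a Spearman rho of 0.408. Each library was also placed on a scale with the P14 mean at 0 and the P24 mean at 1 over the 8546 age genes. This position holds only the part of a change that goes in the direction of the age change. PBS libraries lay at 0.137, 0.203 and 0.084 and rmIl22 libraries at 0.435, 0.398 and 0.366. The highest, 0.435, argues against mice of the labelled day 24, which lay at 0.952 to 1.01, and library 2 at 0.398, above a bound of 0.3211, argues against a pattern of libraries 1 and 3 alone. Paneth cell genes, 1 of 35 lists and chosen for this question after their values were seen, did not rise towards P24 as a list with rmIl22. This argues against a general advance in maturation that takes in these genes. Their lower level was not called (0 of 15 members, camera adjusted p = 0.0668), and the member Ang4 was higher (log2 fold change 0.32). Their median relative to the PBS mean (log2) was 0.88 to 1.05 in the P24 libraries. It was -0.21, -0.41 and -0.35 in rmIl22 libraries 1 to 3, below all PBS libraries (-0.17 to 0.16). For most other genes such an advance cannot be told apart from a further effect of IL-22 or of the injection, because no P24 mice were injected. Fos, Clps and Slc27a4 fell below their P24 level with rmIl22, which an advance that stops at that level does not give. Other differences between the untreated and the injected mice stay open for them. In a limma fit of all libraries 4 of 64 genes higher with rmIl22 were above P24, and 11 of 325 lower with it below P24, at an adjusted p under 0.05 for rmIl22 against P24, a count that misses smaller or more variable differences. Of 342 genes called in both comparisons 8, or 2.339% (1.015 to 4.557), went against the age change, but this share leaves out rmIl22 genes not called between the ages, such as Ifit3 (-2.59 with rmIl22, -0.65 with age), and decides nothing. Of the 10 splits of the 6 libraries, 1 gave as many genes, the real one (389, highest other 0), too few splits for a share under 0.05.

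The rmIl22 group held 2 female libraries and PBS none, as 5 sex-linked genes (Xist, Ddx3y, Eif2s3y, Kdm5d and Uty) parted the 14 libraries in the same way, so sex accounts for the differences in those genes. Over the 368 autosomal rmIl22 genes the median female minus male difference at P14, signed by the rmIl22 change, was -0.08051 (-0.104 to -0.06143), against a bound of 0.2633, which argues against sex as the source of the autosomal changes. That interval resamples genes, not mice, and leaves out the spread between mice. The difference itself rests on 2 female and 2 male P14 libraries. A response to IL-22 that itself differs by sex stays open. With sex as a covariate the rmIl22 change rests on library 1 alone against PBS and tests nothing about sex: the median size was 1.138 against 1.053, and the median SE rose from 0.1593 to 0.2229, so fewer passed.

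More genes were lower than higher at P24 on the deposited scale. With the mitochondrial and 20 most abundant genes left out of the total, the median log2 fold change was -0.197 (-0.2047 to -0.1877), and on recovered reads without length weighting -0.193 (-0.2034 to -0.1826), both below a bound of -0.1227. This argues against either as the whole cause, although both intervals resample genes, not mice, and leave out the spread between mice. Whether less RNA per gene or a wider set of abundant genes lies behind it stays open, because TPM holds no absolute scale. Of the 35 splits of the 8 libraries, 1 gave as many genes, the real one (8546, highest other 1). That share is under 0.05 and the smallest these splits allow, which argues against a random grouping of the libraries for the age count. It says nothing about other differences between the groups, such as sex (P24 3 female and 1 male libraries, P14 2 and 2).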
